A study of Homo sapiens with 6 samples.

How the data were processed

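The series holds 6 RNA libraries of Ovcar8 cells, 3 cultured with 5% FBS and 3 without serum for 48 h, grouped by the treatment given in the labels; the replicate number comes from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and column cleanup with DNase, libraries were made with a NEBNext Ultra II RNA kit and sequenced on an Illumina NovaSeq. Per the submitters' processing notes, STAR 2.6.1, DESeq2 and the genome build GRCh38 were used; their roles, the counting tool and whether counting used strand are not given in the sources used here. The deposited table gives, per gene and library, raw counts and FPKM values made by the authors, with gene coordinates, length and biotype per the file headers. Its 58735 gene IDs and all 58735 start and end positions matched GENCODE 29, as did 58708 symbols. The deposited counts were whole numbers. In all 6 libraries the deposited FPKM equalled the count divided by gene length and by the DESeq2 size factor times the geometric mean of the library totals (ratio 1 for genes above 20 counts), so they carry a between-library scaling.

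The counts were the main measurement and the FPKM values an alternative. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 13772, libraries were scaled with TMM, and the groups were compared with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-normalized CPM as mean ± SD, and the SE of a log2 fold change is its size divided by the square root of the F statistic. The common dispersion corresponded to a biological coefficient of variation of 36.3%. A count of 3 in a library, the limit that a count of 0 allows, corresponded to 0.153 to 0.183 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

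Before the data were examined, 23 gene lists were fixed, with the test, the alternatives and the rule for named genes. The rule took the 10 largest increases and the 10 largest decreases among protein-coding genes that passed, had a mean of at least 5 CPM and did not overlap between groups (6 decreases met it), up to 2 passing members per list and direction, and 13 fixed genes. It gave 30 tested genes, of which some are not reported here; FST was below the filter. Other called genes and list members written by name were chosen after their values were seen. List members were matched by symbol or, for older symbols, through a gene name table. Lists were tested two-sided with camera in limma 3.58.1, preset correlation 0.01, adjusted over the 23 lists. Of the 10 lists that passed, none passed with an estimated correlation. In fry, which tests whether a list's genes move on balance in a single direction without comparing them with other genes, the cholesterol list passed (adjusted p = 0.0277) and the other lists did not. With the GC and length correction the cholesterol list (0.0287) and the fatty acid, ribosome biogenesis and other cell type lists (each 0.0358) passed fry. Median, mean and camera direction differed in sign for the DNA replication list (median 0.00, mean -0.04, down), the histones (-0.18, 0.05, up), the p53 targets (-0.0022, -0.02, up), the immediate early genes (-0.08, 0.19, down) and the glycolysis list (-0.01, 0.08, up). GC content came from the GENCODE 29 transcript sequences, as the mean over a gene's transcripts, for 13768 of the 13772 genes.

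The alternatives in the plan were DESeq2 size factors (RLE), total counts alone, no low-count filter, a stricter filter (1 CPM and 10 counts in 3 libraries), DESeq2 1.42.0, limma-voom and no robust estimation. They were also a replicate block, each library left out, thinning to equal depth, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5 or without a filter, an adjusted p under 0.01, protein-coding genes only, a minimum fold of 1.2 and, for the lists, camera on ranks. After seeing the data, a per-library correction for GC content and gene length (splines with 5 degrees of freedom entered as offsets), voom with sample quality weights and 1 surrogate variable (sva 3.50.0) were added.

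The tests were run on simulated data drawn from the means and library sizes of this comparison. With 13388 genes run and no GC trend, the main test recovered 12 of 99 genes changed 2-fold and 75 of 96 changed 4-fold, with 5 false among 92 calls. With the libraries' GC and length trends added and 13410 genes run, it recovered 3 of 96 and 52 of 94, with 2 false among 57 calls, and the GC and length correction recovered 18 of 96 and 70 of 94, with 4 false among 92 calls. The simulated spread came from the uncorrected counts, which already hold these trends. The added trends came from the same spline model that the correction removes. These recoveries therefore cannot measure the gain from the correction in the real libraries. In camera, 3 of 100 simulated unchanged lists had a p under 0.05. The simulated genes were drawn independently and the lists at random. The result therefore cannot tell how often camera with the preset correlation passes real lists whose genes are correlated.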

Results

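RNA was sequenced from Ovcar8, an established human cell line of high-grade serous ovarian cancer. Cells were kept for 48 h in RPMI-1640 medium with 5% fetal bovine serum (FBS, the usual source of growth factors and lipoproteins in culture) or for the same time without serum, with 3 libraries in each group. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries. The libraries with FBS held 17882533, 17292872 and 16379416 counts assigned to genes, in the order of the replicates. The serum-starved libraries held 17288356, 18201183 and 19558484. The log2 CPM of the libraries (counts scaled to the library total) correlated at 0.904 to 0.975 (Pearson, across genes) within groups and at 0.911 to 0.973 between groups. The first principal component held 38.9% of the variance, and its gene loadings correlated with transcript GC content at a Spearman rho of 0.702 across 13768 genes, which are not independent replicates. The second component held 31.2%, and its loadings correlated at -0.01 with GC content and at -0.32 with gene length. Its scores separated the groups: 43.2, 29.3 and 25.6 with FBS and -19.7, -4.29 and -74.2 in serum-starved libraries, in the order of the replicates. GC content separated libraries inside each group. From the lowest to the highest GC decile of genes, the median log2 deviation ran from 0.79 to -0.27 in FBS replicate 1. It ran from -0.70 to 0.49 in serum-starved replicate 1 and from 0.29 to -0.47 in serum-starved replicate 3. From the shortest to the longest decile by gene length, it ran from -0.53 to 0.47 in serum-starved replicate 3. In those deciles the other libraries lay between -0.18 and 0.21. Serum-starved replicate 3 also had the lowest score on the second component, so that component cannot be read as an effect of serum alone.

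**Figure D1:**
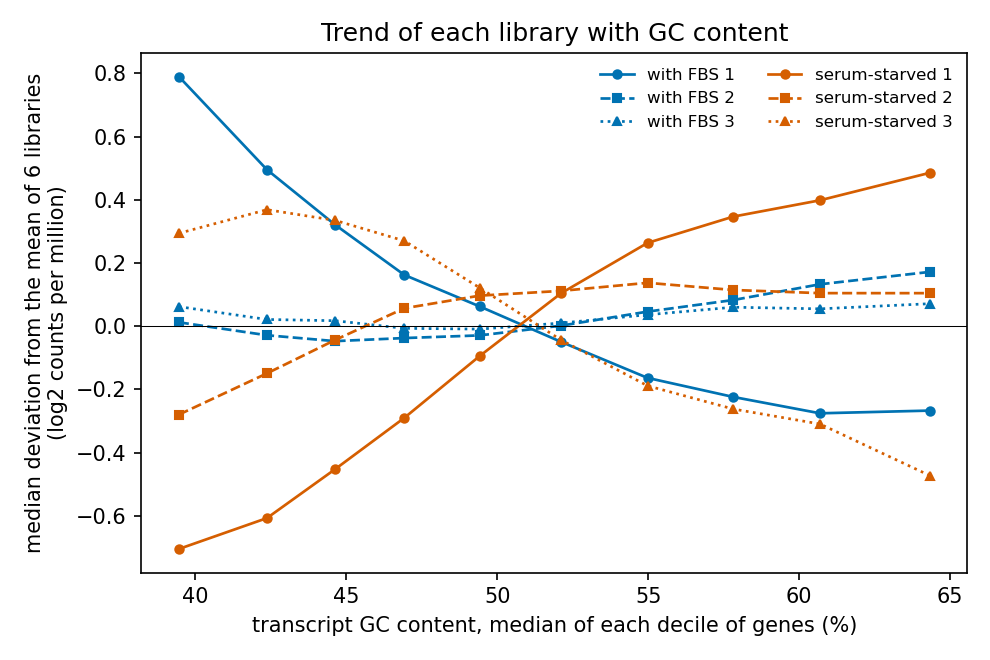
Median deviation of each library from the mean of the 6 libraries (vertical axis, log2 CPM) against the median transcript GC content of each decile of the tested genes (horizontal axis, percent), with 1 line per library, blue with FBS and orange serum-starved. The lines of FBS replicate 1 and serum-starved replicate 3 slope down with GC content and the line of serum-starved replicate 1 slopes up.

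The comparison asked which transcripts differ after 48 h without serum, a condition the series title links to quiescence, the reversible exit from the cell cycle. Without serum, 16 genes of the cholesterol and fatty acid lists rose. HMGCS1, a synthase early in cholesterol synthesis, rose 5.43-fold, and SCD, the stearoyl-CoA desaturase, rose 6.38-fold. ID3 and ID1, inhibitors of basic helix-loop-helix transcription factors and targets of BMP signalling, fell 20.04-fold and 5.63-fold. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 39 of 13772 genes changed (33 higher and 6 lower in serum-starved cells), all 39 by at least 2-fold, and 16 of the 39 belonged to the cholesterol or fatty acid lists. The test had little power for smaller changes. It recovered 12 of 99 simulated 2-fold changes without a GC trend and 3 of 96 with the libraries' GC and length trends. A gene that did not pass may therefore still have changed. At an unadjusted p under 0.05 there were 1430 genes, 828 higher and 602 lower. The groups did not overlap in 2437 genes, 17.7% of those tested. The mean share over all 10 splits of the 6 libraries into 3 and 3 is 10% for genes without ties. Genes move together, so a single split can lie above this mean without an effect of serum. The shares of the other splits were not computed. The count moved when single libraries were left out: it was 4 without FBS replicate 1, 14 without FBS replicate 2 and 20 without FBS replicate 3. It was 65 without serum-starved replicate 1, 16 without serum-starved replicate 2 and 257 without serum-starved replicate 3 (124 higher and 133 lower). All 39 genes kept their direction in each of these fits. The groups did not overlap in any of the 39, so leaving out a library could hardly turn a direction. The kept directions are therefore no evidence of stability. A fit with fewer libraries also has less power, which by itself can lower the count. With a per-library correction for GC content and gene length, added after seeing the data, 121 genes changed (101 higher and 20 lower), 38 of them among the 39.

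**Figure D2:**
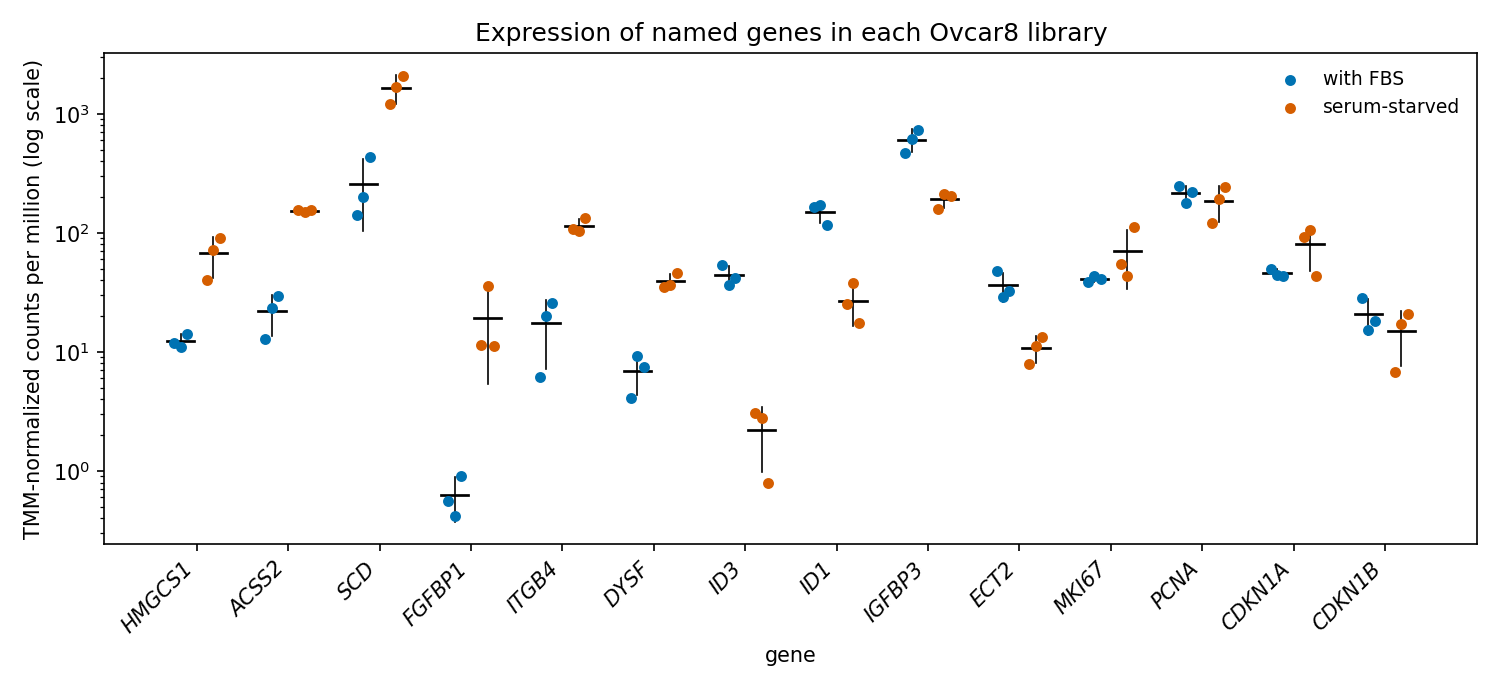
TMM-normalized CPM (log axis) of 14 named genes in each of the 6 Ovcar8 libraries, blue with FBS and orange serum-starved, with the group mean (horizontal bar) and its SD (vertical bar, n = 3). The groups do not overlap for HMGCS1, SCD, ID1 and ID3 and overlap for PCNA, CDKN1A and CDKN1B.

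Of the 26 measured genes of cholesterol synthesis and uptake, 9 rose, none fell and 17 did not pass the test over all genes. Adjusted over the list alone, 22 were higher and none lower. This adjustment, here and for the other lists, does not cover the 23 lists. In a list where most genes move, it also lets larger p-values pass than the test over all genes. HMGCS1 (ENSG00000112972, chromosome 5, 43289395 to 43313512, GRCh38) rose from 12.4 ± 1.65 to 67.3 ± 25.2 CPM (SD, n = 3 per group), a log2 fold change of 2.44 with a standard error (SE) of 0.34 and an edgeR adjusted p of 0.00227. Among the others that rose were INSIG1, TM7SF2, DHCR7, LSS, ACAT2, SQLE and MVD, with log2 fold changes from 1.62 to 2.37. The list stood above all other genes in the camera test with a preset correlation (median log2 fold change 1.34, adjusted p = 1.69e-36), and its adjusted p was 0.0836 with an estimated correlation. HMGCS1 lost its call without FBS replicate 1, at an edgeR adjusted p of 0.0979.

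Of the 26 measured genes of fatty acid synthesis and desaturation, 7 rose, none fell and 19 did not pass. Adjusted over the list alone, 11 were higher and none lower. ACSS2, which makes acetyl-CoA from acetate (ENSG00000131069, chromosome 20, 34872146 to 34927962), rose from 21.9 ± 8.39 to 154 ± 3.68 CPM (SD, n = 3; log2 fold change 2.82, SE 0.33, edgeR adjusted p = 0.000641). SCD (ENSG00000099194, chromosome 10, 100347124 to 100364834) rose from 260 ± 155 to 1656 ± 447 CPM (log2 fold change 2.67, SE 0.42, edgeR adjusted p = 0.00665). FASN, the fatty acid synthase, reached 3669 ± 639 CPM from 898 ± 425 CPM, and FADS2, the delta-6 desaturase, 706 ± 112 from 180 ± 99.4 CPM. The other 3 that rose do not make or desaturate fatty acids: PNPLA3 is a lipase and retinyl esterase of lipid droplets, LPIN1 a phosphatidate phosphatase, and TMEM97 a membrane protein that binds the cholesterol transporter NPC1. PNPLA3 (ENSG00000100344, chromosome 22, 43923739 to 43964488) rose from 4.73 ± 2.28 to 25.3 ± 8.09 CPM (log2 fold change 2.43, edgeR adjusted p = 0.0121). In camera the list passed with the preset correlation (median log2 fold change 0.60, adjusted p = 1.24e-15), and its adjusted p was 0.131 with an estimated correlation. SCD and PNPLA3 lost their calls without FBS replicate 1 (edgeR adjusted p = 0.194 for SCD and 0.277 for PNPLA3) and without FBS replicate 2 (0.0516 and 0.0871). Of the 52 members of the cholesterol and fatty acid lists together, 16 passed. The number was 1 without FBS replicate 1, 4 without FBS replicate 2, 12 without FBS replicate 3, 20 without serum-starved replicate 1, 6 without serum-starved replicate 2 and 26 without serum-starved replicate 3.

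**Figure D3:**
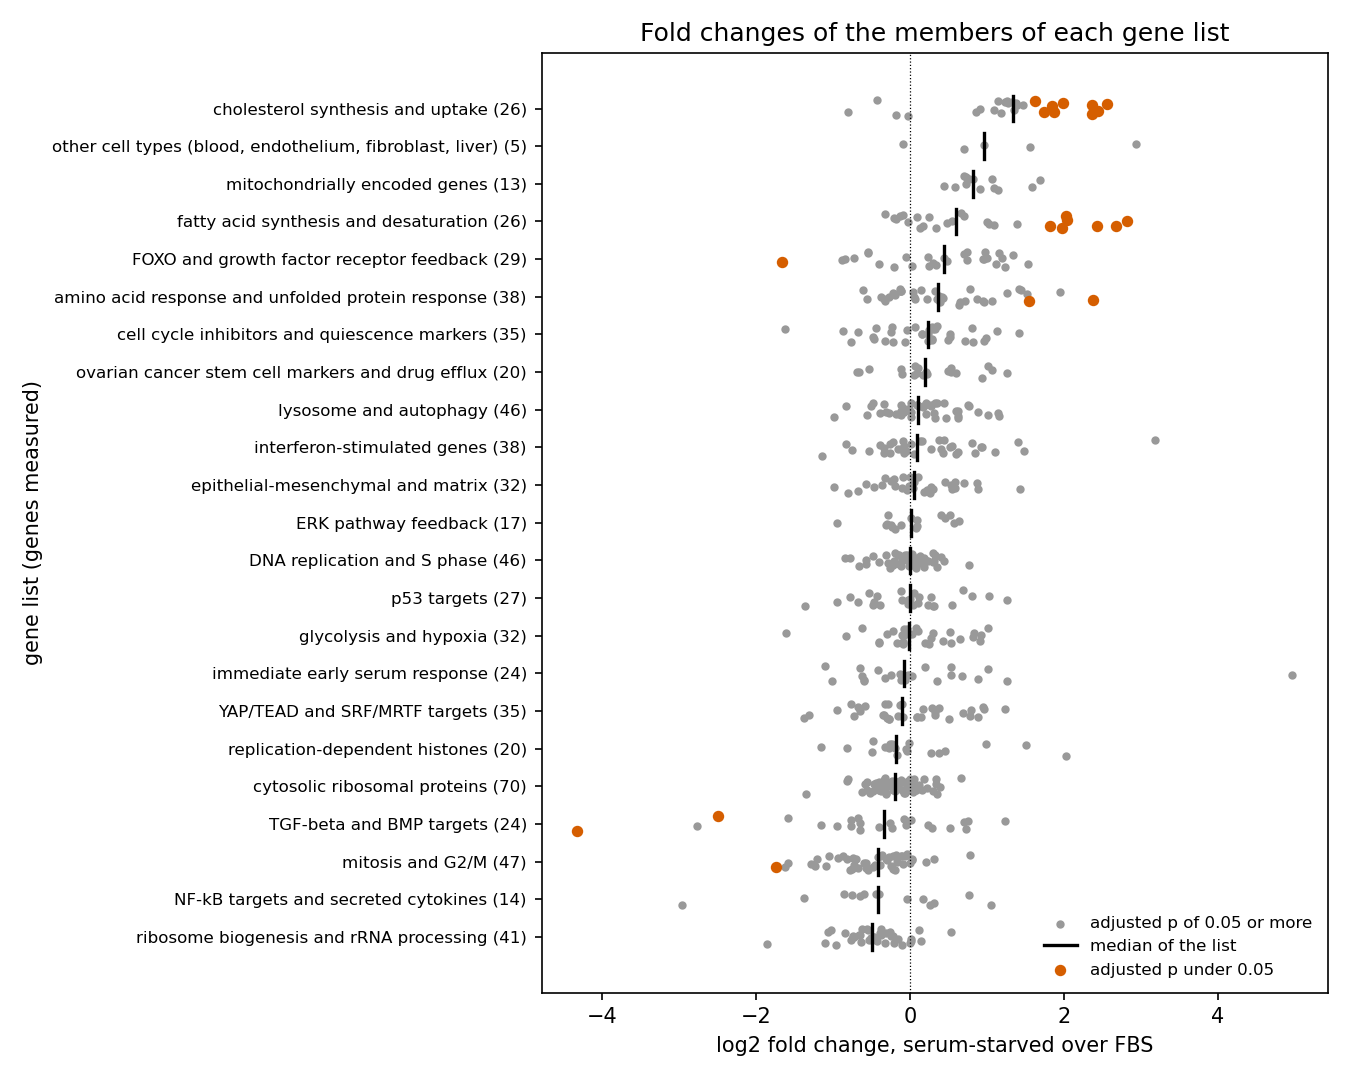
Log2 fold change of each measured member (points) of the 23 gene lists, serum-starved over FBS, with orange points for genes at an edgeR adjusted p under 0.05 and a black bar at the median of each list; the number of measured genes follows the name of the list. The cholesterol list has its median at 1.34, the DNA replication list at 0.00, and the mitosis list at -0.42.

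Of the 39 genes, 6 fell, against 133 that fell and 124 that rose without serum-starved replicate 3. ID3 (ENSG00000117318, chromosome 1, 23557918 to 23559794) dropped from 43.8 ± 8.51 to 2.22 ± 1.24 CPM (SD, n = 3; log2 fold change -4.32, SE 0.45, edgeR adjusted p = 0.000308). ID1 (ENSG00000125968, chromosome 20, 31605283 to 31606515) dropped from 151 ± 30.6 to 26.8 ± 10.1 CPM (log2 fold change -2.49, SE 0.34, edgeR adjusted p = 0.00186). They were the 2 of 24 measured TGF-beta and BMP targets that passed, over all genes and adjusted over the list alone, and no member rose. That list's median was -0.33 (camera adjusted p = 0.00312), with an adjusted p of 0.195 with an estimated correlation, of 0.155 in camera on ranks and of 0.0602 without serum-starved replicate 1. The median was -0.14 without serum-starved replicate 1 and -0.55 without serum-starved replicate 3. IGFBP3, a secreted protein that binds insulin-like growth factors (ENSG00000146674, chromosome 7, 45912245 to 45921874), fell from 606 ± 132 to 191 ± 29.03 CPM (log2 fold change -1.67, SE 0.31, edgeR adjusted p = 0.0269). BIRC2, an inhibitor of apoptosis (ENSG00000110330, chromosome 11, 102347211 to 102378670), fell from 10.99 ± 5.31 to 2.15 ± 0.804 CPM (log2 fold change -2.34, edgeR adjusted p = 0.0463). SNAPC1, a subunit of the complex that starts small nuclear RNA transcription (ENSG00000023608, chromosome 14, 61762357 to 61796428), fell from 26.6 ± 7.73 to 7.66 ± 1.67 CPM (log2 fold change -1.80, edgeR adjusted p = 0.0322). With the GC and length correction the log2 fold change of SNAPC1 was -0.93 and its call was lost (edgeR adjusted p = 0.101). ID3 passed in all 6 fits that left out a library and ID1 in 5, its edgeR adjusted p being 0.0549 without FBS replicate 1. BIRC2, SNAPC1 and ECT2, described with the mitosis genes, passed in 1 of the 6, the fit without serum-starved replicate 3. IGFBP3 passed in 2, without serum-starved replicate 1 and without serum-starved replicate 3.

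Among cell cycle genes, none of the 46 measured genes of DNA replication and S phase passed, over all genes or adjusted over the list alone, and the list's median log2 fold change was 0.00 (camera adjusted p = 0.747). PCNA, the sliding clamp of DNA polymerases, was at 215 ± 34.2 CPM with FBS and 185 ± 60.8 CPM without serum (SD, n = 3; edgeR adjusted p = 0.861). Of 47 measured genes of mitosis and G2/M, 41 had a fold change below 0, ECT2 fell, none rose and 46 did not pass. The number that passed was 6 without serum-starved replicate 3 and 0 in each of the other 5 fits that left out a library. Adjusted over the list alone, 3 were lower (ECT2, CDK1 and HMMR) and none higher. ECT2, an exchange factor that starts the cleavage furrow (ENSG00000114346, chromosome 3, 172750682 to 172821474), fell from 36.2 ± 10.1 to 10.8 ± 2.79 CPM (log2 fold change -1.74, SE 0.34, edgeR adjusted p = 0.031). The mitosis list passed camera with the preset correlation (median -0.42, adjusted p = 3.49e-07), and its adjusted p was 0.231 with an estimated correlation. MKI67, the proliferation marker Ki-67, had a fold change above 0 that did not pass, at 40.7 ± 2.39 CPM with FBS and 69.8 ± 36.3 CPM without serum (log2 fold change 0.78, SE 0.34, edgeR adjusted p = 0.426). Its log2 fold change was 0.27 without serum-starved replicate 3. The mitosis genes had a median transcript GC content of 45.3%, against 50.7% over all genes tested, and with the GC and length correction their median log2 fold change was -0.19 (camera adjusted p = 0.000526, and an adjusted p of 0.667 with an estimated correlation). Of 20 measured replication-dependent histone genes none passed (camera adjusted p = 0.884). CCND1, which encodes cyclin D1, was at 423 ± 73.0 CPM with FBS and 358 ± 47.1 CPM without serum (edgeR adjusted p = 0.832).

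No gene of the list of cell cycle inhibitors and quiescence markers passed over all genes (35 measured, median 0.24, camera adjusted p = 0.222); adjusted over the list alone, PNRC1 and BHLHE40 were higher and none lower. With the GC and length correction these 2 passed over all genes (edgeR adjusted p = 0.00208 for PNRC1 and 0.0217 for BHLHE40). The list's camera adjusted p with the preset correlation was 0.0399 without FBS replicate 1 and 0.0226 without serum-starved replicate 1. With an estimated correlation and all libraries it was 0.723. Its median was 0.08 without serum-starved replicate 2 and -0.07 without serum-starved replicate 3. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was at 45.9 ± 3.63 CPM with FBS and 80.1 ± 32.5 CPM without serum (SD, n = 3; log2 fold change 0.80, edgeR adjusted p = 0.397). Without serum-starved replicate 3, CDKN1A passed at an edgeR adjusted p of 0.0183. CDKN1B, which encodes p27, was at 20.7 ± 6.87 and 14.9 ± 7.30 CPM (edgeR adjusted p = 0.74), RBL2, the pocket protein p130, at 13.3 ± 1.11 and 15.6 ± 10.7 CPM (0.895), and TXNIP, the thioredoxin-interacting protein, at 8.83 ± 4.004 and 10.8 ± 3.32 CPM (0.86). Of 27 measured p53 targets none passed over all genes (camera adjusted p = 0.884), and SESN2 was higher and none lower adjusted over the list alone. Of 24 measured immediate early genes of the serum response none passed over all genes (camera adjusted p = 0.913); adjusted over the list alone, NR4A2 and EGR1 were higher and PLAUR was lower. NR4A2 rested on 1 count over the 3 libraries with FBS and 43 over the 3 serum-starved libraries, a ratio per total of 40.3 with an exact binomial 95% interval of 6.85 to 1627 that covers counting error only. MYC was at 142 ± 2.96 CPM with FBS and 132 ± 59.5 CPM without serum (edgeR adjusted p = 0.937), and FOS at 2.39 ± 1.68 and 3.49 ± 1.57 CPM (0.81). None of 17 measured genes of ERK pathway feedback passed, over all genes or adjusted over the list alone (camera adjusted p = 0.884). Of 35 measured YAP/TEAD and SRF/MRTF targets none passed over all genes (camera adjusted p = 0.747), and ANKRD1 and TAGLN were lower and none higher adjusted over the list alone.

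Among 29 measured genes of FOXO and growth factor receptor feedback, IGFBP3 fell, none rose and 28 did not pass. Adjusted over the list alone, 6 were higher (FOXO3, ERBB3, TSC22D3, IRS2, IGF1R and PDGFRB) and IGFBP3 was lower. The list passed camera with the preset correlation in the upward direction (median 0.45, adjusted p = 0.00312), and its adjusted p was 0.231 with an estimated correlation and 0.125 with the GC and length correction. Of 38 measured genes of the amino acid response and unfolded protein response, 2 rose, none fell and 36 did not pass. Adjusted over the list alone, 7 were higher and none lower. DDIT4, an inhibitor of mTORC1 signalling (ENSG00000168209, chromosome 10, 72273920 to 72276036), rose from 6.71 ± 1.16 to 34.8 ± 22.9 CPM (SD, n = 3; log2 fold change 2.38, SE 0.43, edgeR adjusted p = 0.0225). SLC1A4, a transporter of neutral amino acids (ENSG00000115902, chromosome 2, 64988477 to 65023865), rose from 20.1 ± 3.81 to 58.8 ± 18.8 CPM (log2 fold change 1.55, SE 0.32, edgeR adjusted p = 0.0479). The list passed camera with the preset correlation (median 0.37, adjusted p = 0.000174), and its adjusted p was 0.421 with an estimated correlation and 0.103 without serum-starved replicate 2, where the median was 0.11. DDIT4 and SLC1A4 each passed in 2 of the 6 fits that left out a library, without serum-starved replicate 1 and without serum-starved replicate 3.

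None of 41 measured genes of ribosome biogenesis passed, over all genes or adjusted over the list alone, although 36 had a fold change below 0. As a group they stood below the other genes in camera with the preset correlation (median -0.49, adjusted p = 1.28e-06), with an adjusted p of 0.21 with an estimated correlation. Their median was -0.29 without FBS replicate 1. None of 70 measured cytosolic ribosomal protein genes passed, over all genes or adjusted over the list alone (median -0.20, camera adjusted p = 0.0267, 0.812 with an estimated correlation). That list's median was 0.02 without serum-starved replicate 3 (camera adjusted p = 0.695), -0.11 without FBS replicate 3, -0.36 without serum-starved replicate 1 and -0.07 with the GC and length correction. Its camera adjusted p was 0.0851 without FBS replicate 3, 0.0572 without serum-starved replicate 2 and 0.183 with the GC and length correction. All 13 mitochondrially encoded protein genes had a fold change above 0 and none passed over all genes. Adjusted over the list alone, 5 were higher (MT-ND6, MT-ND5, MT-ND4L, MT-CYB and MT-CO1) and none lower (median 0.82, camera adjusted p = 2.65e-09, 0.266 with an estimated correlation). The median was 0.53 without serum-starved replicate 1 and 1.32 with the GC and length correction. Mitochondrial genes took 2.08% ± 0.526 of counts with FBS and 3.91% ± 1.25 without serum (SD, n = 3), with 2.50% in serum-starved replicate 2 below the 2.68% of FBS replicate 3.

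For the lysosome, interferon, glycolysis, NF-kB, epithelial-mesenchymal and stem cell lists, camera did not pass and no member passed over all genes. Of 46 lysosome and autophagy genes, TPP1, ULK1 and NPC1 were higher and none lower adjusted over the list alone (median 0.11, camera adjusted p = 0.0585). Of 38 interferon-stimulated genes, OAS3 and USP18 were higher and none lower adjusted over the list alone (median 0.10, camera adjusted p = 0.115). Of 32 genes of glycolysis and hypoxia, ADM, which encodes adrenomedullin, was lower and none higher adjusted over the list alone (median -0.01, camera adjusted p = 0.691). Of 14 NF-kB targets and secreted cytokines, MMP1 and CXCL5 were lower and none higher adjusted over the list alone (median -0.42, camera adjusted p = 0.227). In the 32 genes of epithelial-mesenchymal state and matrix (camera adjusted p = 0.347) and the 20 ovarian cancer stem cell markers and drug efflux genes (0.0622), none passed adjusted over the list alone. NFATC4, a calcineurin-regulated transcription factor on the stem cell list, was at 34.4 ± 11.3 CPM with FBS and 40.1 ± 5.71 CPM without serum (SD, n = 3; edgeR adjusted p = 0.862). Some camera results passed in other settings, all with the preset correlation. With an estimated correlation and all libraries, the camera adjusted p was 0.49 (lysosome), 0.421 (interferon), 0.703 (NF-kB) and 0.421 (stem cell). The lysosome list passed without FBS replicate 2 (adjusted p = 0.0334), FBS replicate 3 (0.0247) and serum-starved replicate 3 (0.00507). The interferon list passed without serum-starved replicate 3 (0.0099), and the NF-kB list without FBS replicate 3 (0.0162). The stem cell list passed without FBS replicate 1 (0.0399), FBS replicate 2 (0.0497) and serum-starved replicate 1 (0.00382). Its median was 0.19 with all libraries, 0.33 without FBS replicate 1 and 0.39 without FBS replicate 2. With the GC and length correction the interferon list passed (0.0433), with an adjusted p of 0.454 with an estimated correlation. Without single libraries the median ranged from 0.06 to 0.29 for the lysosome list, from 0.06 to 0.19 for the interferon list, from -0.05 to 0.14 for the glycolysis list and from -0.62 to -0.12 for the NF-kB list. The lysosome median was 0.06 without serum-starved replicate 1 and 0.29 without serum-starved replicate 3, and the NF-kB median was -0.12 without FBS replicate 1. The lysosome list also passed with total counts alone (0.0497) and with the stricter filter (0.0455). FST, which encodes follistatin, was below the count filter, with 19, 8 and 0 counts in the libraries with FBS and 3, 7 and 58 in the serum-starved libraries.

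Of 24 markers of blood, endothelium, fibroblasts and liver, 5 passed the count filter, among them COL1A1, PDGFRB and VWF. None passed the test over all genes, and VWF and PDGFRB were higher and none lower adjusted over the list alone. The 5 stood above other genes in camera with the preset correlation (median 0.97, adjusted p = 0.000481), with an adjusted p of 0.231 with an estimated correlation. Their median was 0.64 without FBS replicate 1. Their most abundant member was COL1A1, at 489 ± 148 CPM with FBS and 796 ± 34.5 CPM without serum (SD, n = 3), while VWF was at 0.347 ± 0.114 and 2.72 ± 1.45 CPM. COL1A1 and PDGFRB also stand on the TGF-beta and the FOXO list.

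Some of the largest increases lay outside the lists. FGFBP1, a secreted carrier of fibroblast growth factors (ENSG00000137440, chromosome 4, 15935569 to 15938740), rose from 0.629 ± 0.254 to 19.4 ± 14.02 CPM (SD, n = 3; log2 fold change 4.95, SE 0.57, edgeR adjusted p = 0.000597). FGFBP1 was at 35.6 CPM in serum-starved replicate 2, against 11.4 and 11.3 CPM in the other serum-starved libraries. Without that replicate its log2 fold change was 4.16. ITGB4, the integrin subunit beta 4 that anchors epithelial cells to laminin (ENSG00000132470, chromosome 17, 75721328 to 75757818), rose from 17.3 ± 10.1 to 115 ± 16.2 CPM (log2 fold change 2.73, SE 0.41, edgeR adjusted p = 0.00568). EPPK1, the cytoskeletal linker epiplakin (ENSG00000261150, chromosome 8, 143857324 to 143878464), rose from 1.69 ± 0.594 to 12.4 ± 5.71 CPM (log2 fold change 2.86, edgeR adjusted p = 0.0139). CPA4, a carboxypeptidase (ENSG00000128510, chromosome 7, 130293134 to 130324180), rose from 3.16 ± 1.199 to 22.6 ± 9.85 CPM (log2 fold change 2.84, edgeR adjusted p = 0.00625). DYSF, the membrane repair protein dysferlin (ENSG00000135636, chromosome 2, 71453722 to 71686768), rose from 6.96 ± 2.61 to 39.3 ± 5.87 CPM (log2 fold change 2.50, edgeR adjusted p = 0.00312). OLFML2A, ADM2, NPR1, PLAT, PPP1R3G, SEMA3B, LAMA5 and PKD1 also rose, with log2 fold changes from 1.46 for PKD1 to 2.29 for OLFML2A. FGFBP1, ITGB4, ACSS2 and ID3 were the 4 of the 18 called genes named by rule that passed in all 6 fits that left out a library. Without FBS replicate 1 the edgeR adjusted p was 0.26 for EPPK1, 0.143 for CPA4 and 0.0665 for DYSF; it was 0.091 for EPPK1 without FBS replicate 3 and 0.0878 for CPA4 without serum-starved replicate 2. EPPK1 consists of near-identical repeats. The genes ITGB4, ACSS2, PNPLA3, TM7SF2, LAMA5, ACAT2, FADS2, PKD1 and RBL2 overlap a gene counted at 10% or more of their own mean count. Their counts depend on how the authors' counting treated shared reads.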

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

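The correction for GC content and length, the sample weights and the surrogate variable were chosen after seeing the data. The 39 called genes kept their direction in every alternative except log2(FPKM + 1) and log2(FPKM + 0.1) with a filter, which each tested 37 of them and kept those. In these 39 genes the groups did not overlap, so a turned direction was hardly possible. The number of changed genes moved more. There were 127 changed (83 higher, 44 lower, 127 at least 2-fold) with no low-count filter, 154 (114, 40, 151) in DESeq2, 25 (22, 3, 25) with total counts only, 22 (16, 6, 22) with FPKM + 1 and 19 (12, 7, 19) with FPKM + 0.1. There were 0 (0, 0, 0) in limma with FPKM + 1 and no filter, where 1534 genes had an unadjusted p under 0.05. There were 13 (11, 2, 13) at an adjusted p under 0.01, which follows from the threshold. With protein-coding genes only there were 11 lower genes. The GC and length correction gave 121 (101, 20, 113), sample weights 1396 (751, 645, 626) and 1 surrogate variable 616 (299, 317, 350). All 39 were among the calls with no filter, in DESeq2, with sample weights and with the surrogate variable, 38 with the correction and 23 with total counts only. Apart from the threshold, the cause was not tested. For the 30 genes named by rule, 572 values in the alternatives kept direction and side of the threshold, 92 lost a call, 17 gained it and 7, of PCNA, NFATC4, RBL2 and MYC, turned direction without a call in either. For the 23 list tests, 267 kept both, 26 lost a call, 13 gained it, 15 turned direction without a call in either and 1 reversed.

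Leaving out 1 library gave 4 to 257 changed genes, 3 to 124 higher, 1 to 133 lower and 4 to 254 at least 2-fold, and shared 4, 14, 19, 36, 13 and 39 of the 39 calls in the order of FBS and serum-starved replicates. The sample weights ranged from 0.216 to 4.33. The lowest belonged to serum-starved replicate 3 and the highest to serum-starved replicate 2. The camera test of the cytosolic ribosomal proteins reversed its direction without serum-starved replicate 3, at an adjusted p of 0.695, against 8.78e-07 to 0.695 over the 6 fits, and the cause was not tested.

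The replicate numbers were not found to pair the libraries: the deviations of same-numbered libraries from their group means correlated at -0.26, 0.10 and -0.08. With a replicate block there were 43 changed genes (35 higher, 8 lower), 36 of them among the 39.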

Other observations

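The tests of single libraries and their bounds, the splits for the lipid and mitosis genes, and everything that uses the GC and length correction were chosen after the data were seen. The basement membrane list was assembled after ITGB4, LAMA5, EPPK1 and PPL had been seen among the changed genes, so it is not independent evidence of their direction. Genes of the basement membrane and of hemidesmosomes and related junctions, which tie epithelial cells to laminin and to each other, had a fold change above 0 in 20 of 24 measured genes (median 0.66). Of the 24, ITGB4, LAMA5, EPPK1 and PPL rose and 20 did not pass, and the list's camera adjusted p was 0.13 with an estimated correlation, and 0.153 with the GC and length correction as well. LAMA5, the laminin alpha 5 chain, rose from 60.7 ± 20.1 to 233 ± 39.5 CPM (SD, n = 3; log2 fold change 1.94, edgeR adjusted p = 0.0121). PPL, which encodes periplakin, had 2, 2 and 0 counts with FBS and 86, 40 and 72 without serum, a ratio per total of 46.4 with an exact binomial 95% interval of 17.8 to 172. Of the members that did not pass, ITGA3 was at 689 ± 206 and 1291 ± 125 CPM, and LAMB2 at 139 ± 35.3 and 280 ± 47.4 CPM.

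With the correction for GC content and length, 18 genes of the cholesterol list, 9 of the fatty acid list and 5 of the amino acid list passed, all higher in serum-starved cells. FDPS, IDI1 and FDFT1 were among those that passed with the correction and not without it, with log2 fold changes from 1.33 to 1.37 and edgeR adjusted p from 0.00437 to 0.0328. ADM, which encodes adrenomedullin, passed as lower (log2 fold change -1.61, edgeR adjusted p = 0.00599). MT-ND6 and MT-ND5, mitochondrially encoded subunits of complex I, passed as higher (log2 fold change 2.28 and 2.04, edgeR adjusted p = 0.00388 and 0.0245). Members of other lists that passed with the correction and not without it included JUND, USP18 and SESN2, as higher, and TAGLN and PLAUR, as lower, with edgeR adjusted p from 0.0255 to 0.0452. These genes were chosen after their values were seen.

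The cholesterol and fatty acid genes had a median log2 fold change of 1.16 over 52 genes. A GC or length trend between libraries as the whole source is argued against by the median of 1.25 after the correction, and by a range of 1.00 to 1.41 when each library was also left out. A single deviating library is argued against by the lowest median without any 1 library, 1.00 (without serum-starved replicate 3). Of the 10 splits of the 6 libraries into 3 and 3, 1 gave a median as large, the real one, and the highest other was 0.49; 10 splits are too few for a share under 0.05. A response to the absence of serum, which brings lipoproteins, is a candidate explanation that the design names and that was not tested apart from other effects of the medium.

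The mitosis genes had a median log2 fold change of -0.42 over 47 genes. A single deviating library stays open: without serum-starved replicate 1 the median was -0.33, and -0.07 with the correction as well. That library's median deviation from the mean of the 6 libraries was -0.51, against -0.04 and -0.0026 in the other serum-starved libraries. The libraries with FBS were at 0.19, 0.27 and 0.18, so each serum-starved library lay below each of them, most of all replicate 1. A GC or length trend could not be told apart from a change in these genes: the median was -0.19 after the correction (-0.28 to -0.07 without single libraries), and the genes have a median GC content of 45.3%, against 50.7% over all genes tested. Of the 10 splits, 1 gave a median as large, the real one, and the highest other was 0.31 in size, too few splits for a share under 0.05. An exit of some cells from the cycle may also lower these genes, and no test here was aimed at it. The DNA replication list had a median log2 fold change of 0.00 (camera adjusted p = 0.747). The list of cell cycle inhibitors and quiescence markers had a median of 0.24 (camera adjusted p = 0.222). Neither list passed, so these lists give no sign of such an exit.

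For the basement membrane genes, a rise beyond the changed genes was tested on the 20 members that did not pass: after the correction 16 had a fold change above 0, their median was 0.37, and camera gave an adjusted p of 0.00748 with the preset correlation and of 0.32 with an estimated correlation. These genes have a median GC content of 58.4%. The median over all 24 members was 0.51 after the correction, with 0.47 to 0.68 when each library was also left out. This median argues against a GC or length trend as the whole source for the list as assembled. It includes ITGB4, LAMA5, EPPK1 and PPL, whose rise prompted the list. For the 20 members that did not pass, the median went from 0.50 to 0.37 with the correction. A GC or length trend as a source of their rise stays open. A wider rise of the group is therefore a hypothesis found and tested on the same libraries.

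For the 39 changed genes, 1 of the 10 splits gave as many, the real one, and the highest other split gave 0; 10 splits are too few for a share under 0.05.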
